A study of Arabidopsis thaliana with 6 samples.

How the data were processed

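The data were 6 Affymetrix arrays of Arabidopsis stem pieces, 3 mock-treated and 3 treated with NPA, each with values for 22810 probe sets. The deposited values are log2 expression values made with RMA, per the submitters' processing notes, which name RMA and limma without versions. RMA corrects the background, quantile-normalizes the arrays and sums up the probes of each probe set, so the arrays have nearly equal distributions. The values ran from about 2.8 to 14.5 on each array, as log2 values of RMA do. RMA gives no call of whether a transcript was detected, so values near the lower end have no known distance from background, and a fold over such a value is not exact. The steps after RMA, the probe set definitions and any filter are not given in the sources used here. Groups and replicate numbers came from the sample titles. Nothing in the labels says whether the 3 samples of a group came from separate plants, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

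The values were used as deposited, without further normalization or filter. The 64 control probe sets were left out of the tests, which left 22746. Differences were computed as NPA minus mock with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over all probe sets tested, and called at an adjusted p under 0.05. A second count used calls with a log2 difference of at least 1. Annotation and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Adjusted p-values are from limma throughout. Standard errors are limma's moderated ones, and an SD is that of the 3 arrays of a group.

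Probe sets were named from the platform's gene table, with symbols brought up to date from a table of the TAIR10.1 assembly. Of the probe sets, 13513 had exactly 1 gene, 503 had several and 8730 of those tested had no listed gene. Of the first, 13436 were matched by gene number, 48 by locus, 24 by symbol, and 5 kept the name of the platform table. The 13513 probe sets stood for 13355 genes. No coordinates are given.

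Before the data were examined, 30 gene lists and the rule for genes to be named were fixed. For lists, 1 probe set per gene was used, the one with the highest mean over the 6 arrays, and only probe sets with exactly 1 gene. Of 600 gene entries in the lists, without the plastid and mitochondrion, 78 were measured, because many genes had no probe set of their own in the platform table. So most lists were seen only in part, 26 had at least 1 measured member, and the lists of D-type cyclins and their inhibitors, xylem vessels, strigolactone and suberin had 0. A gene called not measured may still be on the array, among the 8730 probe sets with no listed gene. The plastid and mitochondrion lists were to be found by locus pattern, which matched no locus tag in the table, so the chromosome given there was used. The named genes were the 8 largest rises and 8 largest falls among called genes whose groups did not overlap, PXY, WOX4, MOL1 and RUL1, the 4 members with the lowest p of each primary list, and 2 members of every other list with a call or 1 of a list without. The primary lists were those of cambium, auxin response, auxin transport, mitosis, DNA replication, vessels, secondary wall and phloem. Genes named outside this rule were members of the same lists or belong to the closing part, and were chosen after their values were seen. Probe sets without a gene name were also outside this rule, picked as the largest called rises and falls among such probe sets.

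Lists with at least 3 measured members were tested with limma's camera, with a preset inter-gene correlation of 0.01 and, as an alternative, an estimated one, and with fry. List p-values were adjusted over the 14 fixed lists tested, and separately over the 3 lists added later and over the 28 gene families of the closing part. Single values per array, such as medians and 3' to 5' differences, were compared by two-sided exact permutation tests, which with 3 against 3 cannot go below p = 0.1.

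The test was checked on simulated data for the comparison of 3 NPA with 3 mock arrays. The 22746 probe sets had their means and limma's moderated spreads, with normal noise and no correlation between genes. Of 100 probe sets changed 2-fold 96% were called, and of 100 changed 4-fold 100%. Of 213 calls 17, or 8.0%, were false. Probe sets with wider spread and correlated genes may give other shares. The alternatives were a replicate block, quantile normalization once more, arrays centred on their medians, only the brighter probe sets, trended and robust eBayes, each array left out, no probe sets with names ending in _s_at or _x_at, other thresholds, the mean of a gene's probe sets and the estimated correlation. Leaving out mock 1 and NPA 3 together, and an adjustment over the fixed and added lists together, were added after the data were examined.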

Results

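Expression was measured in short pieces of the inflorescence stem of wild-type Arabidopsis thaliana of the Columbia strain. The plants were grown for 3 weeks in short days of 8 h light and 16 h dark and were then moved to long days of 16 h light and 8 h dark. Pieces of 3 mm, taken 2.5 cm above the base of the stem, were collected after 7 days of treatment. In 1 group of 3 samples the treatment held N-1-naphthylphthalamic acid (NPA), a compound that blocks the polar transport of auxin, at 10 mg per g. The other group of 3 samples was mock-treated. Total RNA of each sample was hybridised to 1 Affymetrix array with 22810 probe sets, short groups of probes that each measure a transcript. The number of arrays limits the precision of every value that follows. The study used NPA to stop polar auxin transport and start secondary growth, the thickening of the stem by the cambium, and looked for genes of cambium formation and activity. The single comparison that its design implies is NPA against mock.

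Pearson's r over the probe sets was 0.989 to 0.993 within mock, 0.990 to 0.993 within NPA and 0.982 to 0.991 between the groups, so these ranges overlapped. The first principal component held 42.6% of the variance and set all 3 mock arrays apart from all 3 NPA arrays. The second component held 21.9% and set mock 1 and NPA 3 apart from the other 4 arrays. The median value of an array was 6.25 ± 0.06 in mock and 6.36 ± 0.04 in NPA, on the log2 scale (SD, n = 3 each, two-sided exact permutation p = 0.1). This is the smallest p that 3 arrays against 3 allow, so such a test cannot reach 0.05. The difference between 3' and 5' probe sets of the control genes, a sign of RNA breakdown, was 1.63 ± 0.07 in mock and 1.61 ± 0.07 in NPA for the GAPDH control (n = 3 each, exact permutation p = 1). For the actin control it was 3.49 ± 0.26 and 3.48 ± 0.18 (exact permutation p = 1), and for the ubiquitin control 1.56 ± 0.05 and 1.49 ± 0.04 (exact permutation p = 0.2).

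In stems treated with NPA, GH3.3 and GH3.5 (WES1), which encode auxin-induced enzymes that join auxin to amino acids, were 38.4-fold and 6.79-fold higher than in mock. The GH3.3 fold is not exact, since its mock value of 4.36 lay near the lower quartile of the arrays. CLE44, which encodes a precursor of the TDIF peptide that regulates the cambium, rose 3.79-fold. GH9B13, of a family of cellulose-cleaving glycosyl hydrolases, rose 5.17-fold, and EXPB3, a beta-expansin that loosens walls, rose 4.18-fold. Genes of the secondary cell wall also rose, with IRX10 and IRX15-L at 2.64-fold and 2.51-fold. Fewer genes were lower in NPA, and the largest fall of a named gene was 3.04-fold, for AT5G62360, of a family of pectin methylesterase inhibitors.

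Of 22746 probe sets tested with limma, 683 differed at an adjusted p under 0.05. Of these, 628 were higher in NPA and 55 were lower, so 91.9% were higher. With single arrays left out 304 to 446 differed, and 14 to 42 of them were lower. Such fits have fewer arrays, so a call lost in them can come from that alone. A difference of at least 2-fold was seen in 255 of them, 229 higher and 26 lower. At an unadjusted p under 0.05 there were 3714, of which 2589 were higher and 1125 lower, so 69.7% were higher. The values of the groups did not overlap in 5069 probe sets, or 22.3% of those tested, where 10% would be reached by chance. With each array centred on its own median, which shifted all differences down by 0.11 on the log2 scale, 391 probe sets were higher and 97 lower, so 80.1% were higher. The median difference over all tested probe sets was 0.016 before this centring and -0.093 after it, so the centring itself favoured lower values. Of the 683 probe sets, 341 belonged to exactly 1 listed gene, and by gene 309 were higher and 31 lower.

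The 8 named genes with the largest rise kept their call with each single array left out. GH3.3 went from 4.36 ± 0.30 to 9.62 ± 0.93 (SD, n = 3 each), a log2 difference of 5.26 with a standard error of 0.42 (adjusted p = 0.00237). GH3.5 rose by 2.76 ± 0.27 (SE, adjusted p = 0.00396) and AT5G22460 by 2.54 ± 0.30 (adjusted p = 0.00678). GH9B13 rose by 2.37 ± 0.16 (adjusted p = 0.00184) and AT4G28380 by 2.29 ± 0.19 (adjusted p = 0.00259). AT3G57010, of the strictosidine synthase-like family, rose by 2.24 ± 0.14 (adjusted p = 0.00177), EXPB3 by 2.06 ± 0.21 (adjusted p = 0.00436) and CLE44 by 1.92 ± 0.15 (adjusted p = 0.00236). Among probe sets without a gene name here, 247252_at rose by 2.87 and 256299_at by 2.81, while 261459_at fell by 1.77 and 256598_at fell by 1.71.

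The 8 largest falls of named genes lay between -1.60 and -1.20. AT2G05540, of a glycine-rich protein family, fell from 10.41 ± 0.03 to 8.88 ± 0.25 (SD, n = 3 each), a log2 difference of -1.53 with a standard error of 0.13 (adjusted p = 0.00299). AT5G06570 changed by -1.23 ± 0.14 (SE, adjusted p = 0.00553). AT5G62360 and AT4G15700, a glutaredoxin, both changed by -1.60 (adjusted p = 0.0366 and 0.0266). AT2G39980, of an acyltransferase family, changed by -1.58 (adjusted p = 0.0237), AT5G56100 by -1.27 (adjusted p = 0.0197), AT1G49500 by -1.26 (adjusted p = 0.0378) and AT2G45180, of a lipid transfer protein family, by -1.20 (adjusted p = 0.0162). Only AT2G05540 and AT5G06570 of these 8 kept their call with each single array left out. The other 6 lost it without at least 3 of the 6 arrays, each in turn, with adjusted p up to 0.137.

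Of 8 measured auxin-induced response genes, among 26 listed, 3 rose, led by GH3.3 and GH3.5, and none fell. The count adjusted over the list alone was also 3. The other gene was IAA20, an Aux/IAA gene, which rose by 0.98 ± 0.20 (SE, adjusted p = 0.0482). IAA29 differed by 0.43 (adjusted p = 0.273). LBD16, LBD29 and GH3.1 were measured at 4.30, 4.02 and 4.14 in mock, near the lower quartile of the arrays at 4.22, and differed by 0.04, 0.06 and -0.12. The list lay higher against all other genes (camera, adjusted p = 0.00234, median difference 0.31), but adjusted p = 0.495 with an estimated correlation. The median was 0.16 without NPA 3. Among the brighter probe sets only it was 2.76, the value of GH3.5 itself. Brightness was the mean over all 6 arrays, NPA included, so genes raised in NPA passed more easily. That median therefore gives no support for a shift of the list. IAA20 lost its call without any 1 of the 6 arrays, with adjusted p from 0.0685 to 0.146, and after either rescaling of the arrays. Its difference stayed at 0.77 to 1.11 with single arrays left out.

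Of 25 listed genes of polar auxin transport, the step that NPA blocks, only WAG2 was measured. It encodes a protein kinase that acts on PIN auxin carriers. WAG2 rose by 1.56 ± 0.27 (SE, adjusted p = 0.0255) from a mock value of 4.19, below the lower quartile, and this was 1 of 1 member also when adjusted over the list alone. The call was lost without mock 1, mock 2, mock 3 or NPA 2, with adjusted p up to 0.0805. The auxin synthesis genes YUC2, YUC4 and YUC6 differed by -0.15, -0.13 and 0.01, with 0 of 3 called by limma with either adjustment or at an unadjusted p under 0.05 (camera, adjusted p = 0.401). YUC4 was at 3.61 in mock, also below the lower quartile.

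Of 29 listed cambium regulators, 7 were measured. Of these 7, 2 rose and none fell, and 3 rose when adjusted over the list alone. CLE44 had the largest change. MOL1, a receptor kinase gene of the cambium, rose from 7.20 ± 0.15 to 7.87 ± 0.06 (SD, n = 3 each), a log2 difference of 0.67 with a standard error of 0.11 (adjusted p = 0.0209). CLE41, which encodes the same peptide as CLE44, differed by 0.46 ± 0.13 (SE, adjusted p = 0.132), and ERF018 by 0.46 ± 0.44 (adjusted p = 0.674). The list lay higher against all other genes (camera, adjusted p = 0.00336, median difference 0.46), but adjusted p = 0.324 with an estimated correlation. The study may have chosen MOL1 on these samples, so its place in the list is not independent evidence. MOL1 lost its call without any 1 array but mock 3, with adjusted p up to 0.0773, and with arrays centred on their medians (adjusted p = 0.0515), and the list median was 0.01 without NPA 2. The MOL1 difference stayed at 0.58 to 0.73 with single arrays left out. The cambium genes PXY, WOX4 and RUL1 were not analysed here, as no probe set of their own was named. Of the HD-ZIP III and KANADI regulators only PHV was measured, at a difference of 0.37 (adjusted p = 0.410, 0 of 1 called by limma with either adjustment or at an unadjusted p under 0.05).

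**Figure D1:**
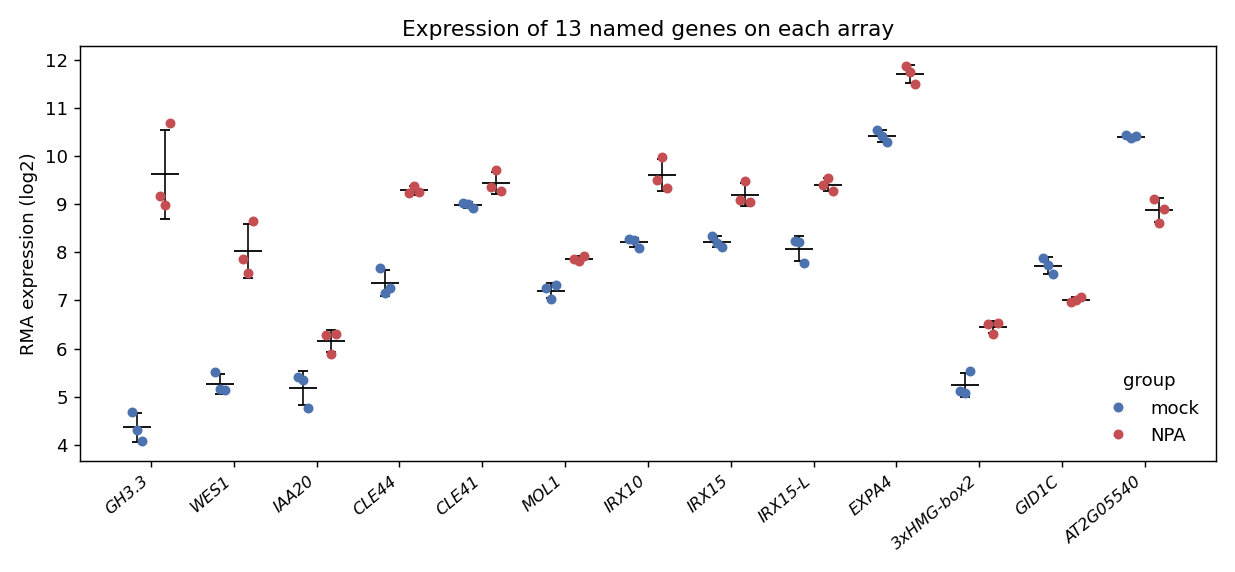
RMA expression on the log2 scale (vertical axis) of 13 named genes (horizontal axis) on the 3 mock arrays (blue) and the 3 NPA arrays (red), with black lines for the mean and 1 SD. GH3.3 lay near 4.36 in mock and 9.62 in NPA, GID1C and AT2G05540 were lower in NPA, and CLE41 is shown although its difference of 0.46 was not called.

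Some genes of mitosis rose in NPA. Of 27 genes listed for G2 and mitosis, 4 were measured. Of these 4, 2 rose, none fell, and 3 rose when adjusted over the list alone. 3xHMG-box2, which encodes a protein that binds mitotic chromosomes, rose 2.32-fold, by 1.22 ± 0.14 (SE, adjusted p = 0.00678). The Aurora kinase gene AUR2 rose 1.69-fold (adjusted p = 0.0326), while AUR1 differed by 0.46 (adjusted p = 0.228) and AUR3 by -0.04 (adjusted p = 0.871). AUR3 was at 3.88 in mock, below the lower quartile of the arrays. The list lay higher against all other genes (camera, adjusted p = 0.00336), but adjusted p = 0.324 with an estimated correlation. AUR2 lost its call without any 1 of the 6 arrays, with adjusted p from 0.0582 to 0.0966, while its difference stayed at 0.63 to 0.85. Of the DNA replication genes, PRL differed by 0.62 (adjusted p = 0.123) and ICU2 by 0.29 (adjusted p = 0.370), so 0 of 2 were called by limma over all genes, 1 when adjusted over the list alone and 1 at an unadjusted p under 0.05. ICU2 was at 3.99 in mock, below the lower quartile too.

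Of 41 listed genes of secondary wall synthesis and its regulators, only 3 were measured. All 3 rose, and all 3 also when adjusted over the list alone. IRX10, a glucuronoxylan synthesis gene, rose from 8.21 ± 0.09 to 9.61 ± 0.33 (SD, n = 3 each), a log2 difference of 1.40 (adjusted p = 0.00705). IRX15-L and IRX15, which also act on xylan, rose by 1.33 (adjusted p = 0.00532) and 0.97 (adjusted p = 0.0138). The list lay higher against all other genes (camera, adjusted p = 7.72e-06), but adjusted p = 0.255 with an estimated correlation. IRX15 lost its call without mock 2 or mock 3, with adjusted p up to 0.0576. Of the monolignol genes, which make the building blocks of lignin, HCT rose from 11.55 ± 0.09 to 12.30 ± 0.04 (SD, n = 3 each, adjusted p = 0.00749) and CCR2 differed by -0.03 (adjusted p = 0.986), so 1 of 2 rose by either adjustment.

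Of 9 measured genes of the primary wall and wall loosening, 2 rose and none fell, by either adjustment. The expansin genes EXPA15 and EXPA4 rose 3.01-fold (adjusted p = 0.0282) and 2.44-fold (adjusted p = 0.00403). EXPA9 differed by -0.23 (adjusted p = 0.427), and 5 genes of wall-modifying XTH enzymes lay between -0.11 and 0.05. The list was not called (camera, adjusted p = 0.389). EXPA15 lost its call without mock 2, NPA 1, NPA 2 or NPA 3, with adjusted p up to 0.0961.

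Of the phloem genes, OPS, which acts in the formation of sieve elements, rose 2.21-fold (adjusted p = 0.0191). SWEET11, a sucrose carrier gene, differed by -0.95 ± 0.24 (SE, adjusted p = 0.0909). Over the list alone both were called, 1 higher and 1 lower. OPS lost its call without mock 1, mock 2 or NPA 1, with adjusted p up to 0.0765, and SWEET11 gained it without NPA 3 (adjusted p = 0.0460).

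The gibberellin receptor genes GID1A, GID1B and GID1C were the 3 measured members of the gibberellin list, and all had lower values in NPA. GID1C fell by 0.71 (SE 0.11, adjusted p = 0.0193). GID1B differed by -0.50 (adjusted p = 0.0505) and GID1A by -0.33 (adjusted p = 0.317), so 1 of 3 fell over all genes and 2 when adjusted over the list alone. The list lay lower against all other genes (camera, adjusted p = 0.000682, median difference -0.50), but adjusted p = 0.255 with an estimated correlation. GID1C lost its call without mock 1, mock 2, NPA 1 or NPA 2, with adjusted p up to 0.0808, and GID1B gained it after quantile normalization (adjusted p = 0.0303) or median centring (adjusted p = 0.0371). The GID1C difference stayed at -0.80 to -0.63 with single arrays left out.

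Among genes of other hormones, 1 passed the test. BRL1, a brassinosteroid receptor gene and the only measured member of its list, rose 1.37-fold (adjusted p = 0.0443), but not without any 1 of the 6 arrays (adjusted p from 0.0927 to 0.159) nor after either rescaling. The cytokinin response genes ARR15 and ARR16 differed by 0.56 (adjusted p = 0.248) and -0.01 (adjusted p = 0.982). ARR16 was at 3.27 in mock, below the lower quartile of the arrays. The ethylene genes RTE1 and EIN3 differed by 0.20 (adjusted p = 0.474) and 0.06 (adjusted p = 0.817), and the jasmonate gene JMT by -0.39 (adjusted p = 0.396). No member of these 3 lists was called by limma with either adjustment, and ARR15 alone was below 0.05 without adjustment.

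Among markers of other tissues, the 6 nuclear photosynthesis genes of the green cortex all had higher means in NPA, with a median difference of 0.19, but none was called by limma with either adjustment or at an unadjusted p under 0.05 (camera, adjusted p = 0.172). PRK, an enzyme gene of the Calvin cycle, differed by 0.41 (adjusted p = 0.347). PSAN and PSAE-1 differed by 0.08 and 0.09, less than the 0.11 shift of median centring. Without NPA 3 this list was called higher (adjusted p = 0.0383), with the preset correlation, while with all arrays and an estimated correlation adjusted p = 0.495. SCL23, of the starch sheath, differed by -0.51 (adjusted p = 0.0594) and was lower when adjusted over its list of 1. It was called after quantile normalization (adjusted p = 0.0490). ACR4, of the epidermis, differed by -0.02 (adjusted p = 0.965), the stomatal lineage gene FAMA by -0.23 (adjusted p = 0.303) and the floral gene SPL by 0.03 (adjusted p = 0.903), with 0 calls by either adjustment by limma in these 3 lists and an unadjusted p under 0.05 for FAMA alone among them. The 3 stomatal genes had a median of 0.03, a mean of -0.02 and no call (camera, adjusted p = 0.727).

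Flavonoid synthesis, defence and reference genes did not pass limma's test, and none of them had an unadjusted p under 0.05. DFR, an anthocyanin synthesis gene, differed by 0.84 ± 0.37 (SE, adjusted p = 0.324), and 0 of 5 flavonoid genes were called by either adjustment (camera, adjusted p = 0.213). Without NPA 3 this list was called higher (adjusted p = 0.0205), with the preset correlation, while with all arrays and an estimated correlation adjusted p = 0.640. The stress gene ZAT10 differed by -0.54 (adjusted p = 0.509). None of the 5 defence genes was called by either adjustment, and their median of 0.11 and mean of -0.03 differed in sign (camera, adjusted p = 0.691). Of 4 reference genes none was called by either adjustment, with a median difference of 0.12 (camera, adjusted p = 0.364) and 0.21 for CACS (adjusted p = 0.340).

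Genes of the organelles had lower values in NPA as lists, but no single gene passed the test. Of 69 genes encoded in the plastid, 59 had a lower mean in NPA, with a median difference of -0.22 and 0 calls by either adjustment. The list lay lower against all other genes (camera, adjusted p = 6.14e-07), but adjusted p = 0.495 with an estimated correlation. The photosystem gene psbJ differed by -0.56 (adjusted p = 0.128). Of 11 genes encoded in the mitochondrion, 9 had a lower mean, with a median of -0.35 (camera, adjusted p = 0.00331), but adjusted p = 0.495 with an estimated correlation, and nad9 differed by -0.51 (adjusted p = 0.108). Without mock 1 the medians of these lists were -0.075 and -0.23, and without both mock 1 and NPA 3, a choice made after the data were examined, neither list was called (adjusted p = 0.427 and 0.112). At an unadjusted p under 0.05, limma gave 12 of the 69 plastid genes and 5 of the 11 mitochondrial genes. The 25S ribosomal RNA probe set was at 11.87 ± 0.11 in mock and 12.18 ± 0.40 in NPA (SD, n = 3 each, exact permutation p = 0.2).

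**Figure D2:**
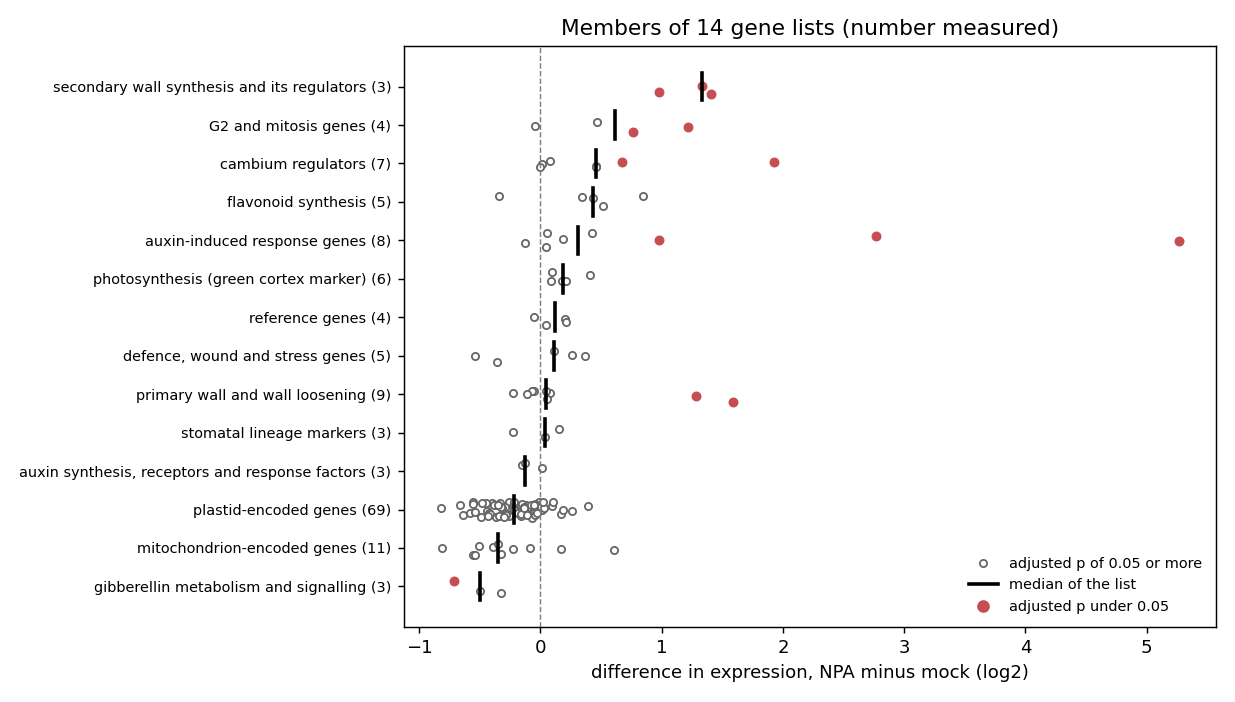
Difference in expression between NPA and mock on the log2 scale (horizontal axis) of each measured member of the 14 tested gene lists (vertical axis), with filled points for an adjusted p under 0.05 and black bars for list medians. All 3 measured genes of secondary wall synthesis were called higher, with a median of 1.33, and the plastid-encoded genes spread around a median of -0.22.

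Of the 14 lists with at least 3 measured members, 7 were called with camera's preset correlation, 4 higher and 3 lower, and with an estimated correlation none was called, with adjusted p of 0.255 or more. By fry, which tests whether a list's genes move on balance in 1 direction and does not compare them with other genes, the adjusted p was 0.0194 for the cambium regulators, 0.0602 for the auxin-induced genes and 0.0105 for secondary wall synthesis. It was 0.0228 for G2 and mitosis, 0.00186 for the gibberellin list, 0.350 for the plastid and 0.269 for the mitochondrion. Among the lists that camera did not call, the lowest was for the reference genes. Their adjusted p of 0.0602 by fry equals that of the auxin-induced genes.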

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

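Leaving out mock 1 and NPA 3 together, and the adjustment over fixed and added lists together, were chosen after the data were examined. Of the 683 called probe sets, 523 were called also after quantile normalization, 445 on median-centred arrays and 609 with the intensity trend. With a replicate block, 449 probe sets were called, 398 of them higher. The shared replicate numbers showed no clear pairing: deviations of same-numbered arrays from their group means correlated at -0.256, 0.0503 and 0.0435, and not every array correlated best with its own number. With 3 arrays per group this cannot exclude a pairing, and the labels do not state one. On median-centred arrays 391 were higher and 97 lower, so 80.1% were higher, and after quantile normalization 87 were lower. At an adjusted p under 0.01, 225 were called, 217 higher and 8 lower, and under 0.1 there were 1208, 1043 higher and 165 lower. Without mock 1 and NPA 3 together 397 were called, 365 higher and 32 lower, with 8 list members. With each array left out in turn, 304 to 446 probe sets were called, 290 to 405 higher and 14 to 42 lower, the fewest without NPA 2. At least 2-fold apart were 185 to 236, with 173 to 221 higher and 10 to 23 lower. The share higher was 89.6% to 95.4%, 7 to 9 lists were called and 8 to 13 list members. These have fewer arrays, and for the other settings the cause was not tested. With an estimated correlation 0 of the 14 fixed lists were called by camera, against 7 with the preset value, and also 0 when adjusted over fixed and added lists together. Of the 30 called named genes, 13 kept their call in every setting and 15 with each single array left out, and none changed sign. Of 25 named genes not called, 4 were called in some setting, namely GID1B, SCL23, SWEET11 and psbJ. Of 54 genes and lists not called, 26 changed the sign of their value in some setting. RMA gives no background level, so no limit from signal over background can be set for dim probe sets.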

Other observations

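The lists and gene families in the next 2 paragraphs were chosen after the annotation had been examined and before any difference between NPA and mock was computed, except that GH9 was separated from GH3 after its values were seen, and the single genes in them were named after their values were seen. Genes whose expression follows the cellulose synthases of the secondary wall in other data, a list from general knowledge, had higher values in NPA. All 14 measured members had higher means in NPA, 7 rose over all genes and 13 when adjusted over the list alone, with a median log2 difference of 0.69. AT1G79620 rose 2.83-fold (adjusted p = 0.0222), AT1G54790 by 1.27 on the log2 scale (adjusted p = 0.00402) and AT1G72230 by 1.19 (adjusted p = 0.0200). The list lay higher against all other genes (camera, adjusted p = 6.93e-16), and with an estimated correlation adjusted p = 0.0161 over the 3 added lists, but 0.0912 over the 14 fixed and 3 added lists together, an adjustment chosen after the result was seen. With single arrays left out 3 to 6 members were called. A second list of mitosis and cytokinesis genes had higher means in NPA for all 21 measured members. Some differed by less than the 0.11 shift of median centring, such as AT1G23790 and 3xHMG-box1 at 0.02 each. Of the 21 members 5 rose, 7 when adjusted over the list alone. They were led by AT4G15830 at 1.08 (adjusted p = 0.00727) and AT3G02640 at 1.01 (adjusted p = 0.0291). The called AT1G72250 and AT5G45700 were at 3.88 and 4.12 in mock, below the lower quartile of the arrays. The list lay higher against all other genes (camera, adjusted p = 2.1e-08), but adjusted p = 0.0917 with an estimated correlation, and only 1 to 4 members were called with single arrays left out. A second list of DNA replication genes had 0 of 6 members called by limma, 1 at an unadjusted p under 0.05 and 1 when adjusted over the list alone (camera, adjusted p = 0.262).

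Of 28 gene families with at least 8 measured members, grouped by the stem of their symbols, 7 were called with the preset correlation and none with an estimated one, where the lowest adjusted p was 0.295. Of the 7, CHR lost its call without NPA 2, and SEC without NPA 1 and among the brighter probe sets only. UBP lost it without mock 1, without NPA 2 and without mock 1 and NPA 3 together. It also lost it after quantile normalization, with the intensity trend and among the brighter probe sets only. Of 22 genes of the TBL family, many of which add acetyl groups to wall polysaccharides, 4 rose. TBL36 rose by 1.84 (adjusted p = 0.00177), TBL39 by 1.71, TBL45 by 0.95 and TBL34, which is also in the second secondary wall list, by 0.65 (camera, adjusted p = 0.000261, and adjusted p = 0.295 with an estimated correlation). Of 15 genes of the GH9 family of cellulose-cleaving glycosyl hydrolases 5 rose, from GH9B7 at 0.99 to GH9B13 at 2.37, with GH9B5, GH9B8 and GH9C2 between them. The GH9 list lay higher against all other genes (camera, adjusted p = 0.00142, and adjusted p = 0.469 with an estimated correlation), with a median of 0.10 that turned to -0.01 on median-centred arrays. The highest GH9 median over all settings was 1.425, but settings that leave out probe sets keep fewer members. That value may not stand for the 15 genes. Of 15 genes of the IQD family of calmodulin-binding proteins 4 rose, among them IQD21 at 0.98 and IQD30 at 0.71 (camera, adjusted p = 0.00115, and adjusted p = 0.295 with an estimated correlation). Of 47 genes of UGT glycosyltransferases 38 had lower means in NPA and 2 fell, UGT85A2 at -1.05 (adjusted p = 0.0271) and UGT72B3 at -0.69 (adjusted p = 0.0449). The UGT list lay lower against all other genes (camera, adjusted p = 0.000261), but adjusted p = 0.507 with an estimated correlation.

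The amounts of poly-A spike-in controls added to each sample, if any, are not known here. Their probe sets had lower means in NPA, by -0.68 for lys (exact permutation p = 0.1) and -0.44 for dap (exact permutation p = 0.4). The differences were -0.41 for thr and -0.40 for phe (both exact permutation p = 0.5), with n = 3 per group. For all 4, mock 1 was the highest mock array and NPA 2 the lowest NPA array, so leaving out either had to shrink the differences, which in the same order were -0.37, -0.23, -0.14 and -0.12 without mock 1 and -0.42, -0.21, -0.23 and -0.18 without NPA 2.

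In the next paragraphs, the tests of an offset between the groups, of green cells and of array mock 1 were chosen after their results were seen. The 6 arrays can be split into 3 and 3 in 10 ways, which is too few for a share under 0.05. The real split gave 683 called probe sets, 255 at least 2-fold apart, 17 called list members and 7 called lists. The highest of the other splits was 0, 0, 0 and 4. Every other split gave 1 to 4 called lists, so list calls with the preset correlation arose under any grouping. The counts of 0 were partly fixed, since mixed groups put any difference between NPA and mock into the spread. At an unadjusted p under 0.05 limma gave 3714 probe sets for the real split and 291 to 1464 for the others. In each case 1 of the 10 splits, the real one, gave as many.

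Of the called probe sets 91.9% were higher in NPA. A uniform offset left by the authors' normalization was weighed by limits set after the result was seen. The median difference over all tested probe sets was only 0.016, which argues against an offset as the only cause. The array medians, though, were 6.25 in mock and 6.36 in NPA. Median centring moved the median difference to -0.093, higher calls from 628 to 391 and lower calls from 55 to 97. Then 80.1% of the called probe sets were still higher, the lower of both scalings. An offset may add to the share and was not excluded. A wider spread of the probe sets that were lower may add to the share and stays open, as the median SE was 0.327 for those at least 2-fold lower and 0.162 for those at least 2-fold higher. Among all probe sets at least 2-fold apart, whatever their p, 79.1% were higher (265 against 70), but 70.8% with the array left out that lowered it most, which is under the 75% set beforehand, and 69.7% of those with an unadjusted p under 0.05 were higher. The treatment itself, which differs between the groups, also stays open, as untested.

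Plastid-encoded genes lay lower in NPA, with a median of -0.22. Fewer green cells in the NPA pieces should lower the nuclear photosynthesis genes too, but these had a median of 0.19, and 0.11 to 0.22 with single arrays left out. The lowest median over all settings was 0.08. Only 6 of 34 listed genes were measured and none was called, so these values weigh only weakly against fewer green cells and do not exclude them. The part of array mock 1 stays open, with a median of plastid-encoded genes of 10.05 on mock 1, 9.66 and 9.69 on the other mock arrays and 9.47 to 9.66 on the NPA arrays. Without mock 1 the difference was -0.075, but this array was chosen for its high value, so leaving it out had to shrink the difference and decides nothing. The treatment stays open too, as untested, and with an estimated correlation the list was not called (camera, adjusted p = 0.495).

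It was also asked whether genes that neighbour each other in the TAIR10.1 gene order were called together, and this was not shown. Of 5852 neighbouring pairs with both genes measured, 6 were called in the same direction, against a mean of 3.13 and a middle 95% of 0 to 7 over 10000 random draws (one-sided permutation p = 0.0954, 0.162 after adjustment over the 2 tests). Among the 6, chosen after their values were seen, were CLE44 with AT4G13190, which rose by 1.92 and 1.60, and the glutaredoxin genes AT4G15700 and AT4G15690, at -1.60 and -1.18. Without probe sets with names ending in _s_at or _x_at the number was also 6, against a mean of 3.69 (permutation p = 0.162). Since the number did not pass the test, cross-hybridization between similar neighbours could not be tested.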
